A study of Mus musculus with 6 samples.

How the data were processed

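Polyadenylated RNA from mouse microglia in vitro was sequenced in 6 libraries: untreated wild type, untreated Cop1 KO and LPS-treated wild type, 2 of each. Per the labels' protocols, RNA was purified on columns with DNase treatment, and libraries were made with a TruSeq RNA kit that does not keep the strand and read single-end on a HiSeq instrument. Reads were aligned by the authors with GSNAP to the mouse genome build GRCm38, per the submitters' processing notes; the GSNAP version and the annotation release are not given in the sources used here. The count values deposited by the authors are numbers of reads aligning uniquely to each gene model, per the file headers. The RPKM values deposited by the authors (nRPKM) are reads per kilobase scaled to depth and multiplied by a size factor per sample, per the file headers; the method behind the size factor is not given. A check showed that the ratio of RPKM value to count between any 2 samples is the same for every gene. The groups follow the treatment labels. The Cop1 KO libraries carry a label that names loxP together with the knockout. The labels give no replicate numbers, batch or pairing.

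The files list 36528 Entrez identifiers, of which 31049 took names and coordinates from RefSeq and 77 from GENCODE, and 5402 had no name. Counts without a name made up 1.072% to 1.304% of each library. Libraries held 21158430 and 22553708 counts (untreated), 21321184 and 21750443 (Cop1 KO) and 22217032 and 20568144 (LPS). The 10 most abundant genes took 13.88%, 16.5% and 8.75% of the counts in the untreated, Cop1 KO and LPS libraries numbered 1.

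Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables were joined with Python 3.11.15. Genes were kept with edgeR filterByExpr by group (15585 genes). TMM factors were 1.192 and 1.190 (untreated), 1.042 and 1.042 (Cop1 KO) and 0.806 and 0.806 (LPS), and CPM values use them. All 6 libraries entered a single quasi-likelihood fit (glmQLFit, glmQLFTest) with group means and 3 residual degrees of freedom, and the common dispersion was 0.00073, a biological coefficient of variation of 2.7%. Cop1 KO with untreated wild type, LPS with untreated wild type, and Cop1 KO with LPS were compared as contrasts. P-values were adjusted by Benjamini-Hochberg over genes and called below 0.05 with no fold minimum. The SE of a log2 fold change comes from the weights of the fit and its quasi-likelihood dispersion. A gene with 0 counts in a group is given as the fold to a floor of 3 counts over that group. The floor leaves out counting error in the higher group, so the lower 95% counting limit is given beside it. A gene with 1 to 3 counts is given as a ratio with a 95% counting interval. List medians with lower bounds place genes at 0 counts at the same floor. These limits and intervals cover counting error only.

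Gene lists were tested with limma camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over 34 lists within each comparison. Members were counted by calls over all genes and by p-values adjusted over the list alone. The lists were the COP1 ligase complex, COP1 substrate transcription factors, inflammatory cytokines, chemokines, interferon-stimulated genes, NF-kB feedback and targets, the TLR4 pathway, acute phase and neutrophil granule genes, homeostatic and disease-associated microglia, complement, antigen presentation, alternative activation, oxidant production, NRF2 antioxidant genes, glycolysis, oxidative phosphorylation, cholesterol synthesis, cholesterol export and LXR targets, lysosome, cell cycle, p53 targets, the unfolded protein and integrated stress response, immediate early genes, heat shock, ribosomal proteins, and markers of astrocytes, the oligodendrocyte lineage, neurons, endothelial and mural cells, fibroblasts, peripheral monocytes and macrophages, dendritic cells and lymphocytes.

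Groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Named genes are Cop1 and Cebpb; the 8 largest increases and 8 largest decreases in the knockout and in the LPS comparison, among called genes with a mean of at least 5 CPM and no overlap between groups, leaving out unnamed gene models; up to 4 members of each called list and up to 2 of each other list, by smallest p; among genes called in both, the 6 most raised, the 6 most lowered and the 8 with the largest opposite changes; and the 5 largest differences in each direction between Cop1 KO and LPS. A named gene may be given in any comparison, and not every list member is printed. Some genes that the rule picks are not reported here and were not replaced, and they stay in all tests of genes and lists. Exon overlap with other genes was taken from GENCODE. Of 193 named genes 56 overlap another annotated entry and 6 do so over more than 20% of their exonic bases. Among the 6, Ddit3 counts only through a second, short entry of the same gene.

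Overlap of calls was set beside the product expected for independent lists, and correlation and covariance beside 20 simulations of unchanged groups against shared controls. Overlap in those simulations is not used, because almost no gene is called where no group differs. The alternatives were median-of-ratios size factors in edgeR, library size only, no low-count filter, a stricter filter, the DESeq2 Wald test, limma-voom, only the 2 groups compared, a fold minimum, a stricter threshold, each library left out, split controls for the correlation, and for lists an estimated correlation and fry. Ranges of list p-values cover the camera settings and leave out fry, which tests each list against no change. A limma fit with a trend on the log2 of nRPKM plus 1 was chosen after the data were seen. The added 1 shrinks changes of genes with low values, so a call lost in that fit need not come from the scaling. The procedure was tested on simulated data with 15138 genes. It recovered 70% of 1.5-fold, 94% of 2-fold and 98% of 4-fold changes in a simulated knockout comparison and 71.4%, 90% and 98% in a simulated LPS comparison. False calls were 17, or 8.72% of calls, and 9, or 4.81%, so the share of false calls can exceed the nominal threshold. All simulated libraries followed the untreated profile, apart from 50 genes changed at each fold, as many up as down. In the real comparisons most tested genes were called, and scaling shifts from such wide changes were not simulated. The rates of recovery and of false calls may therefore not carry over. The changed list was called and 0 others. Splicing, single exons and sequence variants were not analysed here.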

Results

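RNA-seq of polyadenylated RNA was used to compare microglia, the resident macrophages of the brain, kept in vitro in 3 states. The groups were untreated wild-type mouse microglia, untreated microglia labelled as Cop1 knockout (Cop1 KO), and wild-type microglia given lipopolysaccharide (LPS), a bacterial cell-wall component sensed through Toll-like receptor 4. Each group held 2 libraries. The labels give neither the dose nor the duration of LPS. Library totals lay between 20568144 and 22553708 gene counts, so depth differed little between groups. At least 1 count was found for 20041 and 20052 genes in the untreated wild-type libraries, 18797 and 18758 in the Cop1 KO libraries and 19518 and 19464 with LPS. Replicates correlated across genes at r = 0.9989, 0.9989 and 0.9987 for the untreated, Cop1 KO and LPS groups, and their counts differed by more than sampling noise (chi-square per degree of freedom 1.598, 1.995 and 2.568). Nothing in the labels says that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

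Cop1 encodes the ubiquitin ligase that the knockout targets. Its normalised level was 12.7 and 11.5 CPM (counts scaled to the normalised library size) in the untreated wild-type libraries, 8.06 and 9.23 in the Cop1 KO libraries and 23.4 and 27.2 in the LPS libraries. Cop1 (Entrez Gene 26374, chromosome 1, 159232156 to 159354872 on GRCm38) was thus 28.6% lower in Cop1 KO than in untreated wild type (log2 fold change −0.49, SE 0.11, adjusted p = 0.00016, n = 2 libraries per group), and 2.08-fold higher with LPS (1.06, SE 0.10, adjusted p = 1.7e-14). Counts per gene include exons that may lie outside the deleted part, so the reads left in the knockout check the labels only in part. The difference between knockout and wild type did not pass on the authors' normalised scale. That test, limma on the log2 of nRPKM plus 1, was chosen after the data were seen. It gave a log2 fold change of −0.21 (SE 0.08, adjusted p = 0.075, with 5.2e-07 to 0.075 over all alternatives). The added 1 shrinks changes of genes with low values, and with median-of-ratios factors in edgeR the call stayed. Cebpb (Entrez Gene 12608, chromosome 2, 167688915 to 167690432), which encodes a transcription factor that COP1 marks for degradation, was at 93.6 ± 0.458 CPM in untreated wild type, 134 ± 11.2 in Cop1 KO and 322 ± 15.2 with LPS (SD, n = 2). It rose 1.43-fold in the knockout (0.51, SE 0.04, adjusted p = 7e-15) and 3.44-fold with LPS (1.78, SE 0.04, adjusted p = 1.4e-39). In the annotation, 20.7% of its exonic bases overlap Tmem189 on the opposite strand, and the unstranded library does not separate the 2 genes.

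**Figure D1:**
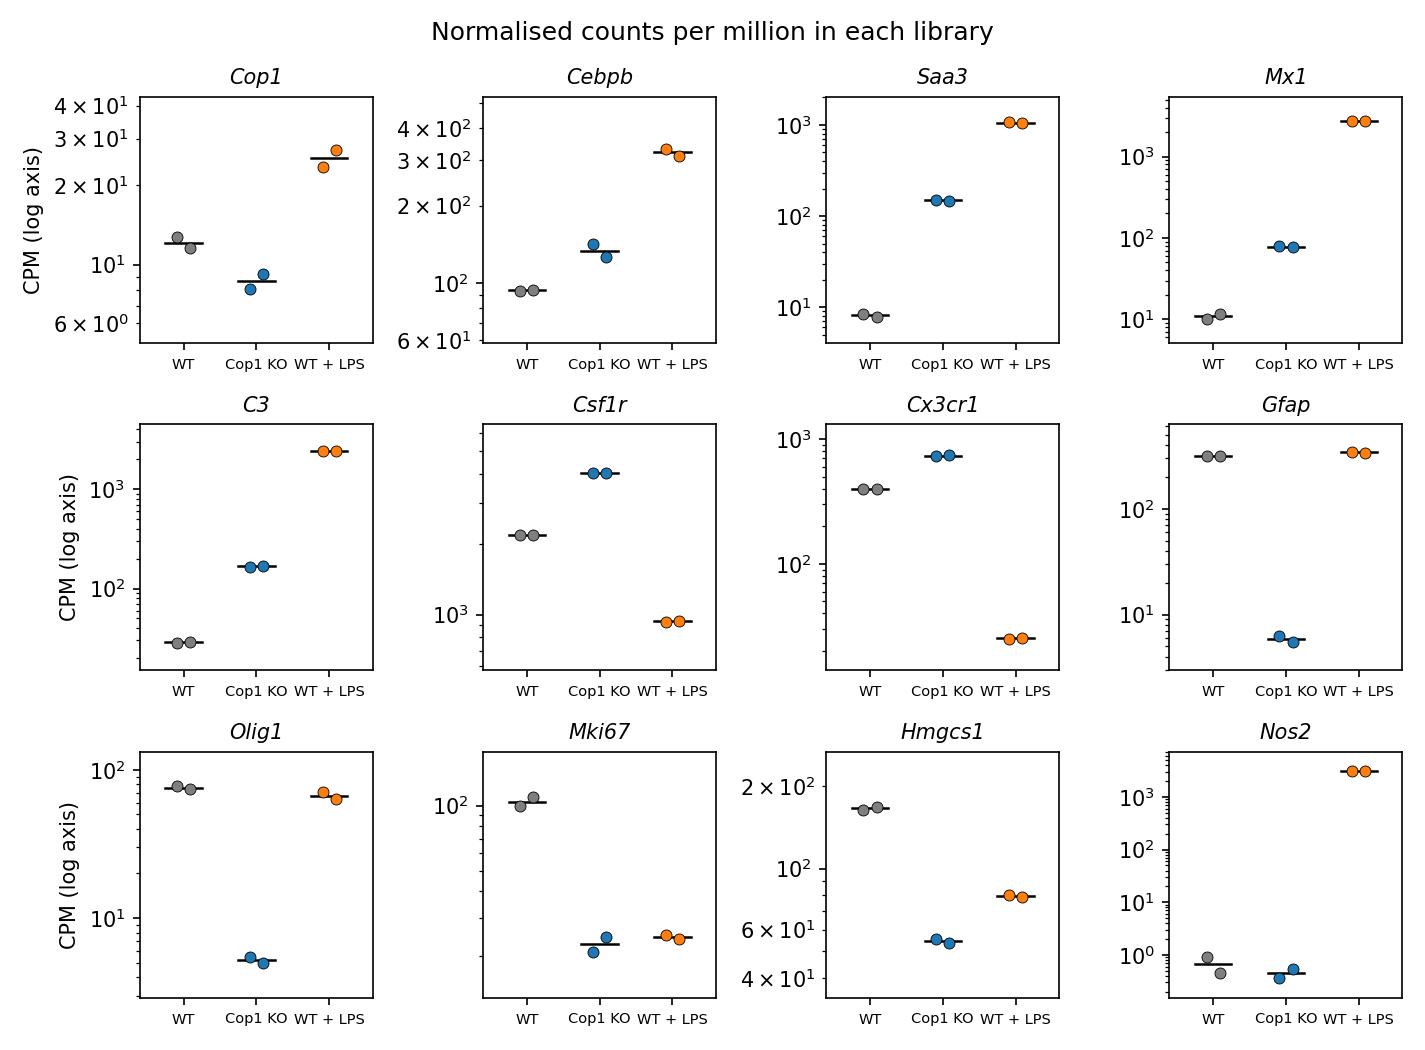
Normalised level (CPM, log axis) of 12 genes in each of the 6 libraries, with points for libraries and bars for group means in untreated wild type, Cop1 KO and LPS-treated wild type. Gfap fell from a mean of 314 CPM to 5.87 in Cop1 KO and stood at 341 with LPS, while Mx1 rose from 10.9 to 78.4 and to 2750.

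The first comparison set Cop1 KO microglia against wild type, both labelled untreated. Cop1 KO libraries held more RNA of interferon-stimulated, complement and acute-phase genes and far less RNA of astrocyte, neuron and cell division genes. All 29 interferon-stimulated genes tested rose, by a median of 1.84 on the log2 scale, and the acute-phase gene Saa3 rose 18.3-fold (4.20, SE 0.07). Of 11 astrocyte markers 10 fell, with a median of −3.83, and Gfap, the astrocyte intermediate filament gene, was 53.5-fold lower (−5.74, SE 0.09). Of 15585 genes tested, 9101 changed (edgeR quasi-likelihood test, n = 2 libraries per group), 4374 higher and 4727 lower. Large changes were mostly decreases: 514 genes rose and 2267 fell by at least 2-fold, and 98 rose and 1544 fell by at least 4-fold. The share of calls that were higher, 48.1%, depended on the scaling: it was 58.4% with median-of-ratios factors, 24.4% with library size only and 63.6% on the authors' normalised scale. The median log2 fold change of all genes was −0.01, 0.08, −0.20 and 0.07 in the same order. Of the 34 gene lists, 16 passed with the preset correlation, 10 higher and 6 lower, and 0 passed with an estimated correlation. The latter setting tests on the 3 residual degrees of freedom, and its p-values were larger also where the estimate lay below the preset. For the astrocyte list the estimate was −0.04, against the preset 0.01. Fry, which tests each list on its own, called 27. Camera instead compares a list with all other genes, many of which fell here. The lysosome, TLR4 pathway and homeostatic microglia lists had mean log2 fold changes of 0.27, 0.32 and 0.38. Relative to all other genes these means were 0.56, 0.61 and 0.67, so part of that distance is the fall of other genes.

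Among the largest increases, Saa3 (chromosome 7, 46711998 to 46719615) went from 8.14 ± 0.496 to 149 ± 1.61 CPM (SD, n = 2; adjusted p = 3e-50). Fpr1 and Fpr2, receptors for formylated bacterial peptides, rose by 4.12 (SE 0.20) and 3.86 (SE 0.30) on the log2 scale. Ifi206 and Ifi205, interferon-inducible genes of the same family, rose by 3.34 (SE 0.13) and 2.94 (SE 0.16). Fpr1 with Fpr2, and Ifi206 with Ifi205, are related genes whose values are uncertain where reads could be shared. Ifnb1, the interferon beta gene, and Tarm1 had 0 counts in untreated wild type and 12 and 10 counts in the knockout. Against the floor they were 4.64-fold and 3.86-fold higher (lower 95% counting limits 3.22 and 2.6). Tarm1 did not pass on the authors' normalised scale (adjusted p = 0.21; 0.00027 to 0.21 over all alternatives). Among the largest decreases, Steap4 had 80 counts in untreated wild type and 0 in the knockout, 23-fold lower at the floor (lower 95% counting limit 18.3). Itgb8, an integrin subunit gene, fell 123-fold from 14.4 to 0.111 CPM. Gap43, S1pr3, Ptprz1, Slc1a3 and Slitrk2 fell by between 5.63 and 5.76 on the log2 scale, and Slc1a3, the glial glutamate transporter gene, went from 131 to 2.61 CPM.

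Interferon-stimulated genes moved as a block: 29 rose and 0 fell (camera adjusted p = 1.5e-18; adjusted p = 0.11 with an estimated correlation). Mx1, an antiviral GTPase gene, rose 7.19-fold (2.85, SE 0.06), Ifit3 by 2.55 (SE 0.05), Irf7, an interferon pathway transcription factor gene, by 2.40 (SE 0.04) and Ifit2 by 2.21 (SE 0.03). Of 16 NF-kB feedback and target genes, 12 rose and 2 fell, among them Nfkbiz (1.22, SE 0.07) and the inhibitor gene Nfkbia (0.89, SE 0.04) (median 0.69, adjusted p = 0.00013; adjusted p = 0.11 with an estimated correlation). Socs3, a cytokine signalling inhibitor gene, fell by 0.55 (SE 0.13). Adjusted over the list alone, 13 rose and 2 fell. In this comparison the counts adjusted over the list alone equalled those over all genes, apart from the NF-kB, cell cycle and COP1 substrate lists. Of 16 genes of the TLR4 pathway, 11 rose and 0 fell, with the co-receptor gene Cd14 at 0.97 (SE 0.03) and Myd88 at 0.60 (SE 0.04) (median 0.29, adjusted p = 0.0012; adjusted p = 0.13 with an estimated correlation). With library size only, 5 TLR4 pathway genes rose and 2 fell, with a median of 0.10. The astrocyte markers in the same libraries had a median of −3.83.

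Cytokine genes were divided. Of 16, 7 rose, 1 fell and 8 did not pass, with a median of 0.45, or 0.26 with library size only, and the list test gave adjusted p = 0.082 (adjusted p = 0.27 with an estimated correlation). Tnf rose by 0.99 (SE 0.05), while Il1rn, which encodes the interleukin 1 receptor antagonist, fell by 1.61 (SE 0.04). Nos2, the inducible nitric oxide synthase gene, and Il12b had log2 fold changes of −0.59 (SE 0.35, adjusted p = 0.2) and −0.29 (SE 0.33, adjusted p = 0.54). Of 21 chemokine genes 9 rose and 4 fell (median 0.41, or 0.21 with library size only, adjusted p = 0.077; adjusted p = 0.26 with an estimated correlation). Cxcl10 rose 6.71-fold (2.75, SE 0.08) and Cxcl16 by 1.22 (SE 0.03), Cxcl9 stood at −0.07 (SE 0.29, adjusted p = 0.87) and Ccl22 fell by 4.01 (SE 0.52). Leaving out 1 library brought the cytokine list past the threshold without untreated replicate 1 (adjusted p = 0.038) or Cop1 KO replicate 1 (0.019), and the chemokine list without untreated replicate 1 (0.036), within ranges over the camera settings of 0.0029 to 0.27 and 0.0029 to 0.26. Of 6 acute-phase and neutrophil granule genes tested, 5 rose and 0 fell (median 1.01, adjusted p = 0.011; adjusted p = 0.19 with an estimated correlation). Hp, the haptoglobin gene, rose 10.6-fold from 0.577 to 6.15 CPM (3.40, SE 0.30). Astrocyte and neuron markers in the same libraries had medians of −3.83 and −4.04.

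Most homeostatic microglia, complement, oxidant production and lysosome genes rose, while astrocyte markers in the same libraries were at a median of −3.83. Of 17 homeostatic microglia genes 12 rose and 2 fell (median 0.33, adjusted p = 0.00097; adjusted p = 0.11 with an estimated correlation), and with library size only 10 rose and 3 fell (median 0.14). The colony-stimulating factor receptor gene Csf1r rose from 2190 to 4040 CPM (0.89, SE 0.03) and the fractalkine receptor gene Cx3cr1 from 396 to 735 (0.89, SE 0.03). Gpr84, which inflammatory stimuli induce, is also on this list and rose by 1.80 (SE 0.08). Its exons overlap an antisense gene over 39.5% of their length. Of 14 complement genes 12 rose and 1 fell, led by C3 at 5.83-fold (2.54, SE 0.04) (median 0.65, adjusted p = 0.00012; adjusted p = 0.11 with an estimated correlation). Of 19 antigen presentation genes 12 rose and 6 fell (median 0.90, adjusted p = 0.0098; adjusted p = 0.33 with an estimated correlation). The class I genes H2-K1 and H2-D1, near-identical in parts and so uncertain, rose by 1.24 (SE 0.03) and 1.09 (SE 0.03), and the peptide transporter gene Tap1 rose by 1.49 (SE 0.04). Of 12 oxidant production genes 10 rose and 0 fell (median 0.69, adjusted p = 0.00015; adjusted p = 0.11 with an estimated correlation), including the NADPH oxidase gene Cybb (0.91, SE 0.03) and Acod1, the itaconate-producing enzyme gene (2.43, SE 0.08). Of 22 lysosome genes 18 rose and 1 fell (median 0.30, adjusted p = 6.6e-05; adjusted p = 0.2 with an estimated correlation), and with library size only 13 rose and 6 fell (median 0.11). The cathepsin gene Ctsb rose by 0.52 (SE 0.02) and Atp6v0d2 fell by 0.86 (SE 0.03). The disease-associated microglia list had 13 genes higher and 8 lower, with a median of 0.12 that became −0.08 with library size only (adjusted p = 0.093; adjusted p = 0.48 with an estimated correlation and 0.043 with no low-count filter, the ends of its camera range). Apoe, a lipid carrier gene, rose by 0.83 (SE 0.03).

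Cell division and sterol genes fell. Of 22 cell cycle genes 21 fell and 0 rose, and 22 fell when adjusted over the list alone (median −1.64, adjusted p = 5.1e-09; adjusted p = 0.11 with an estimated correlation). The proliferation marker gene Mki67 went from 104 to 22.8 CPM (−2.19, SE 0.07), Top2a fell by 2.19 (SE 0.07) and Rrm2 by 2.61 (SE 0.13). Of 18 cholesterol synthesis genes 14 fell and 1 rose (median −0.61, adjusted p = 0.00027; adjusted p = 0.11 with an estimated correlation). Hmgcs1 fell by 1.60 (SE 0.04), whereas Fdft1 rose by 0.53 (SE 0.03). These cell cycle and sterol genes fell in libraries in which the astrocyte markers were at a median of −3.83 and the neuron markers at −4.04.

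Markers of neurons and astrocytes had the lowest medians of all lists. Of 11 astrocyte markers 10 fell and 1 rose (adjusted p = 3.6e-06; adjusted p = 0.11 with an estimated correlation). Clu fell by 3.96 (SE 0.08), the water channel gene Aqp4 fell by 4.48 (SE 0.15), and Aldh1l1 rose by 0.25 (SE 0.09). All 10 neuron markers fell, with a median of −4.04 (adjusted p = 0.00013; adjusted p = 0.11 with an estimated correlation). The microtubule genes Map2 and Tubb3 fell by 4.03 (SE 0.16) and 4.05 (SE 0.25), and Dcx had 132 counts in untreated wild type and 3 in the knockout, a ratio of 37.9 (95% counting interval 12.7 to 186). Of 9 oligodendrocyte lineage markers 6 fell and 2 rose (median −1.77, adjusted p = 0.023; adjusted p = 0.32 with an estimated correlation). Olig1 and Olig2, transcription factor genes of the lineage, had log2 fold changes of −3.86 (SE 0.10) and −4.08 (SE 0.18), Pdgfra fell by 5.03 (SE 0.34), and the myelin gene Mbp rose by 0.53 (SE 0.05). Without either LPS library the oligodendrocyte list did not pass (adjusted p = 0.051; 0.001 to 0.32 over the camera settings). The oligodendrocyte list also did not pass with library size only (camera adjusted p = 0.057) or with only the 2 groups compared (0.051). Endothelial and mural markers went the other way, with 5 of 7 higher and 1 lower (median 0.87, camera adjusted p = 0.041, or 0.24 with an estimated correlation). Their call was lost without Cop1 KO replicate 1 (adjusted p = 0.054) and without either LPS library (0.076), within a range of 0.0029 to 0.24 over the camera settings. The endothelial and mural call was also lost with median-of-ratios factors (camera adjusted p = 0.087) and with only the 2 groups compared (0.076). With no low-count filter it was lost too (camera adjusted p = 0.17), and the mean difference from other genes went from 0.98 to 0.51. Flt1 rose by 0.96 (SE 0.05) and Vwf fell by 0.58 (SE 0.05). Of 10 fibroblast markers 6 were higher and 3 lower, with a median of 0.93 and a mean of 0.12 (adjusted p = 0.2; 0.034 with library size only, within 0.034 to 0.43 over the camera settings). Col1a1 rose by 1.26 (SE 0.06). Monocyte and macrophage markers (3 higher and 3 lower of 8, median −0.01, or 0.08 with median-of-ratios factors, adjusted p = 0.78), dendritic cell markers (2 and 5 of 9, median −0.12, adjusted p = 0.57) and lymphocyte markers (0 and 2 of 2, median −1.26, adjusted p = 0.29) did not pass as lists, and the monocyte test pointed up while median and mean (−0.03) were below 0. The lymphocyte marker Klrb1c lost its call without untreated replicate 1 (adjusted p = 0.14), without Cop1 KO replicate 1 (0.053) and with DESeq2 (0.16), within a range of 0.005 to 0.16.

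With TMM factors, components of the ligase and its targets showed no common direction. Of 10 genes of the COP1 ligase complex 2 rose and 4 fell (camera adjusted p = 0.87, or 0.89 with an estimated correlation). Their median of −0.02 became 0.06 with median-of-ratios factors and 0.10 on the authors' normalised scale. With library size only it was −0.22, with 1 gene higher and 7 lower. The adaptor gene Trib1 rose 3.11-fold from 34.6 to 108 CPM (1.64, SE 0.05), and the related Trib2 fell by 3.78 (SE 0.22). Of 9 genes encoding transcription factors that COP1 targets, 4 rose and 3 fell, and 5 rose and 3 fell adjusted over the list alone. Their median was 0.10, or −0.09 with library size only, and their mean −0.39 (adjusted p = 0.85; adjusted p = 0.89 with an estimated correlation). Etv4 fell by 3.23 (SE 0.25) and Etv5 by 0.98 (SE 0.07). Astrocyte and neuron markers, at −3.83 and −4.04, fell in the same libraries as Trib2, Etv4 and Etv5.

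**Figure D2:**
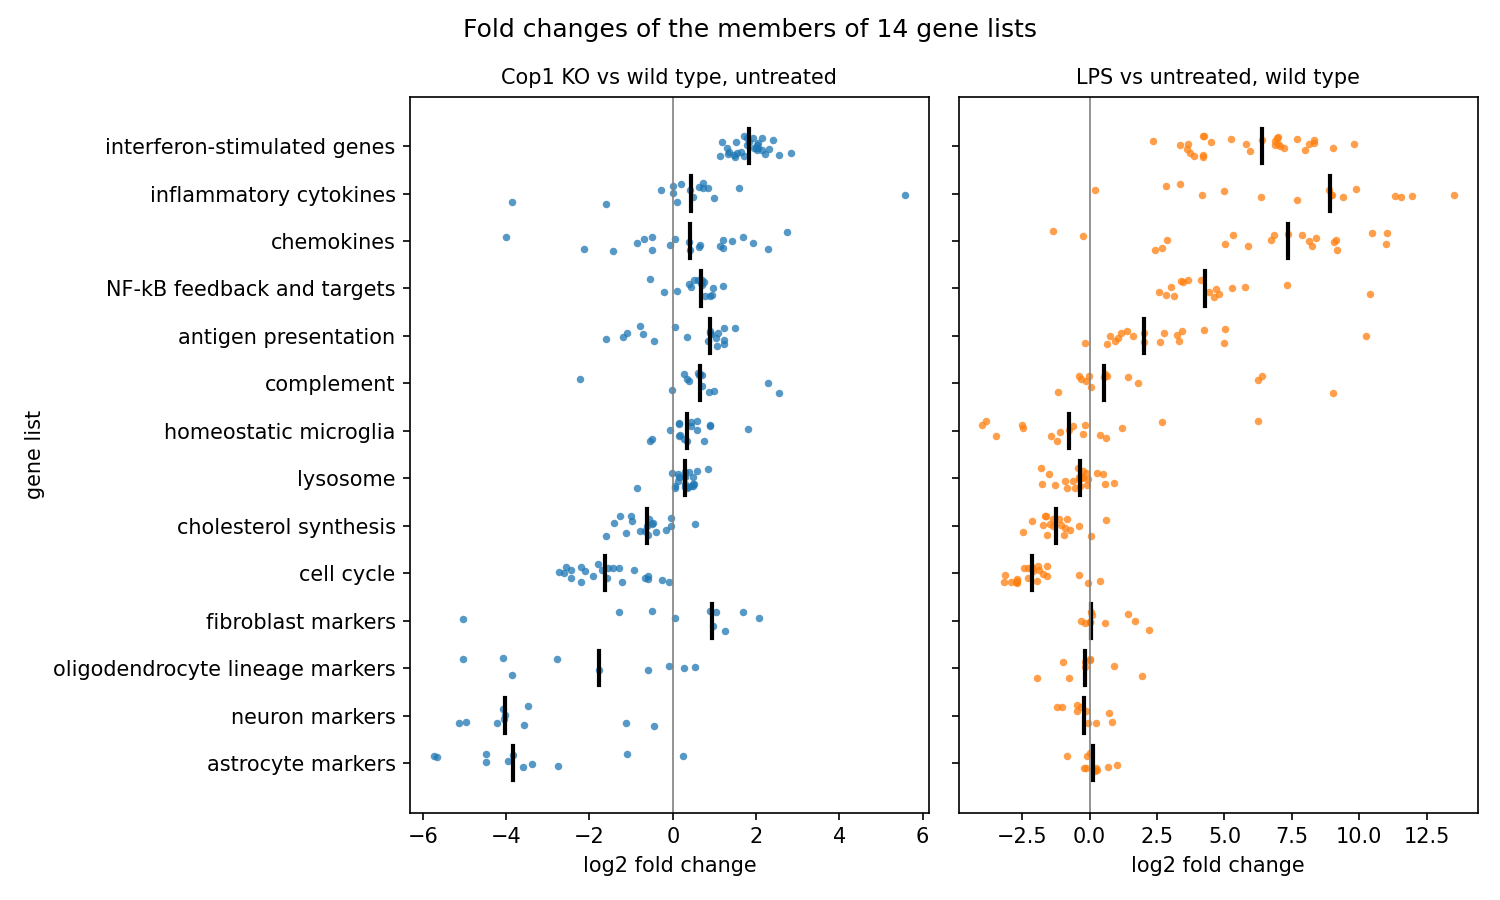
Log2 fold change of each tested member (point) of 14 gene lists in Cop1 KO against untreated wild type and in LPS against untreated wild type, with black bars at the list medians and x axes that differ between the panels. Interferon-stimulated genes have medians of 1.84 and 6.40, and astrocyte markers −3.83 and 0.12, the last becoming −0.45 with library size only.

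The LPS comparison asked how wild-type microglia respond to an inflammatory stimulus, as a reference for the knockout. Cytokine, chemokine, interferon-stimulated and NF-kB genes rose by large factors, while cell cycle and cholesterol synthesis genes fell. Il6 went from 0.118 to 1410 CPM (13.51, SE 0.56) and Nos2 from 0.68 to 3080 (12.15, SE 0.21), with n = 2 libraries per group. Cebpa, a myeloid transcription factor gene, fell 81.7-fold from 394 to 4.8 CPM (−6.35, SE 0.11), and the chemokine receptor gene Cxcr4 fell 169-fold (−7.40, SE 0.22). In all, 11481 of 15585 genes changed (edgeR), 4714 higher and 6767 lower, of which 2326 and 2835 changed by at least 2-fold and 1203 and 889 by at least 4-fold. The share of calls that were higher, 41.1%, was 19.9% with library size only, 51.1% with DESeq2 and 49.6% with median-of-ratios factors, and the median of all genes moved from −0.18 to −0.74, −0.04 and −0.04. Of 34 lists 9 passed, 7 higher and 2 lower, and 0 with an estimated correlation; fry called 28.

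All 16 cytokine genes rose, with a median of 8.93, or 7.13 when genes at 0 counts are placed at their lower bounds (adjusted p = 2.5e-09; adjusted p = 0.076 with an estimated correlation). Il12b rose by 11.97 (SE 0.21), Il1a by 11.31 (SE 0.14), Il1b by 9.39 (SE 0.06) and Tnf by 7.70 (SE 0.05). Ifnb1 had 0 counts untreated and 587 with LPS, 295-fold above the floor (lower 95% counting limit 239). Tnfsf4, Heatr9 and Tarm1 also started from 0 counts and were 1140-fold, 657-fold and 352-fold above it (lower limits 924, 533 and 286). Of 21 chemokine genes 19 rose and 2 fell (median 7.37, or 6.85 with lower bounds, adjusted p = 1.8e-09; adjusted p = 0.076 with an estimated correlation). Cxcl9 rose by 11.04 (SE 0.19), Cxcl10 by 10.48 (SE 0.08) and Ccl5 by 9.13 (SE 0.06). All 29 interferon-stimulated genes rose (median 6.40, adjusted p = 5.6e-19; adjusted p = 0.086 with an estimated correlation), with Rsad2 and Cmpk2 each at 8.32 (SE 0.04). All 16 NF-kB genes rose (median 4.27, adjusted p = 7.7e-11; adjusted p = 0.076 with an estimated correlation), among them Traf1 (10.39, SE 0.24), Socs3 (7.31, SE 0.08) and Icam1 (5.76, SE 0.03). In this comparison the counts adjusted over the list alone equalled those over all genes, apart from the COP1 substrate list.

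Antigen presentation and oxidant genes rose too. Of 19 antigen presentation genes 18 rose and 0 fell (median 2.03, adjusted p = 1.1e-08; adjusted p = 0.17 with an estimated correlation), and the costimulatory gene Cd40 rose by 10.24 (SE 0.12). Of 12 oxidant production genes 9 rose and 3 fell (median 1.54, or 0.97 with library size only, adjusted p = 0.0036; adjusted p = 0.17 with an estimated correlation). Acod1 rose by 10.78 (SE 0.08), the cyclooxygenase gene Ptgs2 by 9.65 (SE 0.07), and Alox5ap fell by 0.92 (SE 0.05). Of 9 dendritic cell markers 6 rose and 0 fell (median 3.55, adjusted p = 0.013; adjusted p = 0.21 with an estimated correlation), or 6 and 3 with library size only (median 2.98). Microglia also express some of these, and Cd83 rose by 3.81 (SE 0.03), Fscn1 by 3.55 (SE 0.04) and Irf8 by 2.61 (SE 0.03). Complement had 8 genes higher and 4 lower of 14 (median 0.55, or −0.01 with library size only, adjusted p = 0.06; adjusted p = 0.3 with an estimated correlation), with C3 at 6.40 (SE 0.04). It passed without untreated replicate 1 (adjusted p = 0.046) and without LPS replicate 2 (0.039), within a range of 0.033 to 0.3 over the camera settings. Of 6 acute-phase and granule genes 3 rose and 1 fell (median 1.16, adjusted p = 0.21; 0.034 with library size only, where the median was 0.60, and 0.034 to 0.49 over the camera settings), with Saa3 at 7.03 (SE 0.07), the lipocalin gene Lcn2 at 5.42 (SE 0.16) and Hp at −0.60 (SE 0.50, adjusted p = 0.26). The TLR4 pathway had 8 genes higher and 5 lower of 16 (median 0.17, or −0.40 with library size only, adjusted p = 0.23), with Myd88 at 2.69 (SE 0.04) and Cd14 at 1.87 (SE 0.03).

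Of 22 cell cycle genes 20 fell and 1 rose with LPS (median −2.13, adjusted p = 1.3e-05; adjusted p = 0.094 with an estimated correlation), including Top2a (−2.68, SE 0.08) and Mki67 (−2.08, SE 0.07). Of 18 cholesterol synthesis genes 16 fell and 1 rose (median −1.23, adjusted p = 0.0013; adjusted p = 0.16 with an estimated correlation), including Dhcr7 (−2.47, SE 0.09) and Msmo1 (−2.13, SE 0.06). The homeostatic microglia list had 12 genes lower and 5 higher of 17 (median −0.78, or −1.35 with library size only, adjusted p = 0.15; adjusted p = 0.41 with an estimated correlation). Cx3cr1 fell 15.7-fold (−3.97, SE 0.05) and Csf1r fell by 1.23 (SE 0.03), while Gpr84 rose by 6.23 (SE 0.07). Disease-associated genes had 18 lower and 6 higher of 24, and here the median (−0.37) and the test pointed down and the mean (0.14) up (adjusted p = 0.23). The protease inhibitor gene Cst7 rose by 6.45 (SE 0.14). Lysosome genes had 17 lower and 4 higher of 22 (median −0.37, or −0.94 with library size only, adjusted p = 0.055), with the lipase gene Lipa at −1.51 (SE 0.03). The lysosome list passed with library size only (adjusted p = 0.023) and with no low-count filter (0.015; 0.015 to 0.49 over the camera settings). Further large decreases were Arhgap19 (−6.66, SE 0.15), Rasgrp3 (−6.04, SE 0.14), Gpr183 (−5.66, SE 0.40), Lhfpl2 (−5.62, SE 0.08) and Dkk2 (−5.47, SE 0.23). Asb10 had 475 counts untreated and 3 with LPS, a ratio of 105 (95% counting interval 35.7 to 510).

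With TMM factors the markers of other cell types, dendritic cells apart, did not pass as lists with LPS, but with library size only those of endothelial and mural cells and of monocytes and macrophages did. Astrocyte markers had 5 higher and 2 lower of 11 (median 0.12, or −0.45 with library size only, adjusted p = 0.4), with Slc1a3 at 0.00 (SE 0.04, adjusted p = 0.98) and Gfap at 0.12 (SE 0.03, adjusted p = 0.0019). Oligodendrocyte lineage markers had 2 higher and 4 lower of 9 (median −0.16, camera adjusted p = 0.84), or 1 and 6 with library size only (median −0.72). Among them Cnp was at 1.92 (SE 0.04) and Mbp at −1.96 (SE 0.08). Neuron markers had 1 higher and 3 lower of 10 (median −0.22, or 0.01 on the authors' normalised scale, camera adjusted p = 0.97). With library size only 0 neuron markers were higher and 7 lower (median −0.78). The calls of Stmn2 (higher) and Rbfox3 (lower) among them were lost without untreated replicate 2 (adjusted p = 0.065 and 0.052) and without LPS replicate 1 (0.062 and 0.093), within ranges of 0.00034 to 0.56 and 5.3e-05 to 0.1. Endothelial and mural markers had 5 higher and 2 lower of 7 (median 1.45, adjusted p = 0.12; 0.0099 and a median of 0.89 with library size only, and 0.0099 to 0.41 over the camera settings), with Kdr at 2.43 (SE 0.08). Fibroblast markers had 4 higher and 1 lower of 10 (median 0.06, or −0.50 with library size only, adjusted p = 0.21), with Postn at 2.22 (SE 0.07). Monocyte and macrophage markers had 5 higher and 3 lower of 8 (median 0.76, adjusted p = 0.1; 0.026 and a median of 0.20 with library size only, and 0.026 to 0.59 over the camera settings), with the integrin gene Itga4 at 2.43 (SE 0.04). Both lymphocyte markers tested were lower (median −1.52, adjusted p = 0.4), but Klrb1c lost its call without untreated replicate 1 (adjusted p = 0.062), without LPS replicate 1 (0.18) and with DESeq2 (0.088), within a range of 0.00028 to 0.18. The COP1 ligase complex had 4 higher and 3 lower of 10 (median −0.07, mean 0.07, camera adjusted p = 0.66). The median was 0.07 with median-of-ratios factors and 0.08 on the authors' scale. With library size only it was −0.64, with 1 gene higher and 8 lower. The COP1 substrate list had 2 higher and 6 lower of 9, or 7 lower adjusted over the list alone (median −0.82, adjusted p = 0.34).

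Genes that changed both in Cop1 KO and with LPS were then counted. Interferon-stimulated genes rose in both and most cell cycle genes fell in both, but the fold changes of all genes were only loosely related. Of the genes called in both comparisons 1874 were higher in both, against 1323 for independent lists, and 2281 were lower in both, against 2052. These counts depended on the processing: 867 were higher in both and 5558 lower in both with library size only. Genes lower in both numbered 1511 with median-of-ratios factors, 893 with DESeq2 and 1244 on the authors' normalised scale. The counts expected for independent lists also change with the number of genes called, and they were not computed for these settings. The 1323 and 2052 are therefore no yardstick for these alternative counts. Opposite changes were fewer than independent lists would give, with 1794 genes higher in the knockout and lower with LPS, against 1899, and 991 the reverse, against 1430. At 2-fold or more, 307 genes were higher in both (independent lists 76.7), 402 lower in both (412), 50 higher in the knockout and lower with LPS (93.5) and 186 the reverse (338). Both comparisons use the same untreated libraries. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.152 and a Spearman rho of 0.162 (0.492 and 0.441 in 20 simulations of unchanged groups against shared controls), and 56.25% had the same sign (simulated 66.5%). In the simulations all variation was noise, partly shared through the controls. Their r, rho and same-sign share are therefore no yardstick for the observed values. The covariance was 0.338 against 0.0359 simulated, a difference of 0.302. With the untreated libraries split, so that each comparison had its own control library, r was 0.154 and 0.151 and the covariance 0.258 and 0.254. Shared controls gave 0.165 and 0.273 on the same log2 CPM scale. The untreated libraries may come from the same culture. Anything they share would then stay in both comparisons, and neither the split nor the simulated covariance removes it.

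Saa3, Fpr1, Fpr2 and Ifi206 were among the genes most raised in both, with log2 fold changes of 4.20, 4.12, 3.86 and 3.34 in the knockout and 7.03, 6.77, 8.23 and 7.29 with LPS. Ifnb1 and Tarm1 also rose in both from 0 counts. The genes most lowered in both have known roles in cell division: Prr11 (−3.01 and −2.99), Bub1 (−2.74 and −3.17), Rrm2 (−2.61 and −2.69), Kif2c (−2.56 and −3.52), Cenpf (−2.49 and −2.72) and Plk1 (−2.45 and −2.71). The strongest opposite changes were all lower in the knockout and higher with LPS. The chemokine gene Ccl22 had −4.01 and 7.37, the actin-bundling gene Fscn1 −3.26 and 3.55, the transcription factor gene Lhx2 −3.33 and 5.34, and Vgf −3.28 and 3.49. Steap4 was 23-fold lower in the knockout at the floor (lower 95% counting limit 18.3) and rose by 3.97 (SE 0.18) with LPS. Shisa3, Upp1 and Tnn had few counts in the knockout (1, 2 and 3, against 29, 21 and 27 in untreated wild type), with ratios of 25 (95% counting interval 4.15 to 1020), 9.06 (2.21 to 79.7) and 7.76 (2.39 to 40). On the authors' normalised scale the knockout decreases of Shisa3, Upp1 and Tnn did not pass (adjusted p = 0.092, 0.12 and 0.3; ranges over all alternatives 9.6e-07 to 0.092, 2e-04 to 0.23 and 0.00011 to 0.3). Without untreated replicate 2 the call for Upp1 was also lost (log2 fold change −1.70, adjusted p = 0.23; 2e-04 to 0.23 over all alternatives). The decreases of these genes in the knockout stand beside astrocyte and neuron markers at medians of −3.83 and −4.04 in the same libraries.

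**Figure D3:**
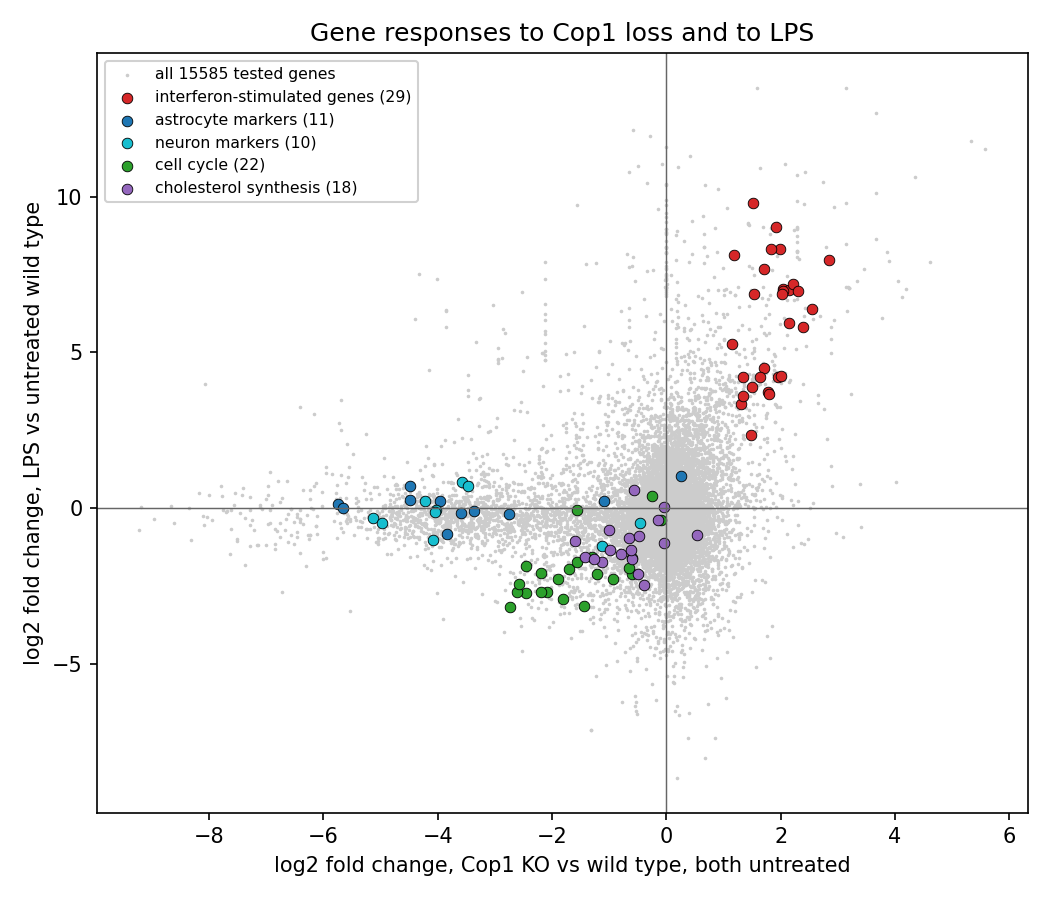
Log2 fold change in Cop1 KO against untreated wild type (x axis) and with LPS against untreated wild type (y axis) for 15585 genes (grey), with 5 gene lists coloured; values of genes at 0 counts in a group depend on the fit. Interferon-stimulated genes lie to the upper right (medians 1.84 and 6.40) and cell cycle genes to the lower left (−1.64 and −2.13). Astrocyte markers (−3.83 and 0.12) and neuron markers (−4.04 and −0.22) lie to the left near 0 on the y axis. With library size only their LPS medians were −0.45 and −0.78. On the authors' normalised scale the LPS median of the neuron markers was 0.01.

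The direct comparison of Cop1 KO with LPS-treated wild type tested whether the knockout and LPS effects differ, and the shared controls cancel in it. Interferon-stimulated, cytokine, chemokine and NF-kB genes were far lower in the knockout than with LPS, and 18 of 22 lysosome genes were higher. All 29 interferon-stimulated genes were lower in the knockout, with a median of −4.12, and Nos2 and Il12b were lower by log2 fold changes of −12.74 (SE 0.28) and −12.25 (SE 0.25). Cxcr4 and Cebpa were higher by 8.25 (SE 0.22) and 6.54 (SE 0.11). Of 15585 genes 12399 differed (edgeR, n = 2 libraries per group), 6220 higher and 6179 lower in the knockout, of which 2729 and 3774 by at least 2-fold. The share higher was 50.2%, or 64.5% with library size only. Of 34 lists 11 passed, 2 higher and 9 lower, and 0 with an estimated correlation; fry called 30.

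Interferon-stimulated genes (adjusted p = 3.3e-12; adjusted p = 0.13 with an estimated correlation) had Gbp5 at −8.27 (SE 0.07) and Rsad2 at −6.48 (SE 0.03). Of 16 cytokine genes 15 were lower and 1 higher (median −8.41, or −6.64 with lower bounds, adjusted p = 9.2e-06; adjusted p = 0.13 with an estimated correlation), with Il6 at −11.93 (SE 0.35). Of 21 chemokine genes 19 were lower and 2 higher (median −7.24, adjusted p = 1.6e-06; adjusted p = 0.13 with an estimated correlation). All 16 NF-kB genes were lower (median −3.70, adjusted p = 1.6e-07; adjusted p = 0.13 with an estimated correlation). Of 19 antigen presentation genes 17 were lower and 2 higher (median −2.23, adjusted p = 5.4e-05; adjusted p = 0.28 with an estimated correlation), and H2-D1 was higher in the knockout by 0.14 (SE 0.03). Dendritic cell markers had 8 lower and 0 higher of 9 (median −3.72, adjusted p = 0.003; adjusted p = 0.22 with an estimated correlation). Steap4 was 362-fold lower at the floor (lower 95% counting limit 293). Shisa3 had 1 count against 3552, a ratio of 4630 (95% counting interval 830 to 183000).

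Homeostatic microglia genes were higher in the knockout than with LPS in 11 of 17 cases and lower in 5 (median 1.06, adjusted p = 0.047; adjusted p = 0.28 with an estimated correlation), with Cx3cr1 at 4.86 (SE 0.05) and Csf1r at 2.11 (SE 0.03). That call was lost without untreated replicate 1 or 2 (adjusted p = 0.065 each) and without LPS replicate 1 (0.056) or 2 (0.063) and with library size only (0.12), within a range of 0.017 to 0.28 over the camera settings. Of 22 lysosome genes 18 were higher and 1 lower (median 0.67, or 1.04 with library size only, adjusted p = 0.00019; adjusted p = 0.28 with an estimated correlation), with the cholesterol transporter gene Npc1 at 1.32 (SE 0.03). Arhgap19 and Dkk2 were higher by 6.89 (SE 0.15) and 6.42 (SE 0.23), and Asb10 had 286 counts against 3, a ratio of 73.2 (95% counting interval 24.8 to 357). Trib1 was higher by 1.41 (SE 0.06) and Cebpb lower (−1.27, SE 0.04). Astrocyte markers were lower in all 11 cases (median −3.44, adjusted p = 8e-05; adjusted p = 0.13 with an estimated correlation), and neuron markers in 8 of 10 (median −4.07, adjusted p = 0.019; adjusted p = 0.28 with an estimated correlation). The oligodendrocyte lineage list had 7 lower and 2 higher of 9 (median −1.78, adjusted p = 0.082; 0.025 with library size only and 0.021 with no low-count filter, within 0.021 to 0.51 over the camera settings). Cell cycle genes had 12 higher and 3 lower of 22 (median 0.34, or 0.71 with library size only, adjusted p = 0.07) and cholesterol synthesis genes 12 higher and 3 lower of 18, or 4 lower adjusted over the list alone (median 0.40, or 0.77 with library size only, adjusted p = 0.077). The cell cycle list passed without LPS replicate 2 (adjusted p = 0.046; 0.02 to 0.28 over the camera settings), and the cholesterol list without Cop1 KO replicate 2 (0.042; 0.021 to 0.28).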

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

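Of 333 pairs of a named gene and a comparison, 12 changed their call or direction under any alternative fixed beforehand other than the fold minimum, which ended 70 calls. The nRPKM fit was chosen only after the data were seen. No paired analysis was possible because the labels give no replicate numbers. With groups of 2, leaving out a library leaves a lone library whose spread is assumed to be like that of the others. Depth limits the genes near 0 counts, which carry floors or counting intervals.

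With a minimum absolute log2 fold change of 1, called genes numbered 2781 (514 higher, 2267 lower) for Cop1 KO with untreated, 5161 (2326 and 2835) for LPS with untreated and 6503 (2729 and 3774) for Cop1 KO with LPS. Genes called in both numbered 307 higher, 402 lower and 236 opposite, and Cop1 at −0.49 lay below the minimum, all by construction. With library size only, 2319 genes were higher and 7200 lower in the knockout, 2678 higher and 10770 lower with LPS, 867 higher in both and 5558 lower in both. Genes lower in both numbered 1511 with median-of-ratios factors, 893 with DESeq2 and 1244 with nRPKM. In the limma fit on the log2 of nRPKM plus 1, Cop1 had −0.21 (adjusted p = 0.075, with 5.2e-07 to 0.075 over its alternatives). The added 1 also shrinks changes of genes with low values. Leaving out TMM factors shifts all log2 fold changes of a comparison by nearly the same amount. The median of all genes moved from −0.01 to −0.20 in the knockout and from −0.18 to −0.74 with LPS. The library-size counts go with that shift. For the other differences apart from the fold minimum the cause was not tested. The correlation of both comparisons was 0.262 with no low-count filter and 0.178 with a stricter filter, where the genes differ by construction, and 0.123 to 0.180 when 1 library was left out; the cause was not tested. With library size only, the LPS changes of Atp5a1 and Atp5b turned to −0.04 and −0.07, in the direction in which the median of all genes moved with LPS. Counts of changed genes stayed between 7605 and 9255, 10567 and 11578, and 11781 and 12267 when 1 library was left out.

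Lists called numbered 0, 0 and 0 with an estimated correlation, and 27, 28 and 30 with fry, for Cop1 KO with untreated, LPS with untreated and Cop1 KO with LPS. With an estimated correlation camera tests on the 3 residual degrees of freedom. In the knockout the estimates of the astrocyte, complement and cell cycle lists (−0.04, −0.04 and −0.02) lay below the preset 0.01. A higher correlation therefore does not account for the loss of those 3 calls. Estimates lay above the preset for interferon-stimulated (0.08), lysosome (0.10), antigen presentation (0.12), oligodendrocyte lineage (0.14) and oxidative phosphorylation genes (0.21). For these lists the part of the correlation in the loss was not tested. With library size only 14 passed for LPS with untreated. The cause of that count and of the fry counts was not tested. Of 102 list tests, the call stayed the same in 98 with median-of-ratios factors, 90 with library size only, 92 with no low-count filter and 96 with only the 2 groups compared.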

Other observations

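Of the energy and stress lists, only oxidative phosphorylation passed with the preset correlation and TMM factors. Of 24 oxidative phosphorylation genes 17 fell and 2 rose in Cop1 KO (limma camera adjusted p = 0.047; adjusted p = 0.55 with an estimated correlation), where median and mean (both −0.15) and the test pointed down while the mean relative to all other genes was 0.14. With median-of-ratios factors 8 fell and 3 rose (median −0.06). Atp5b fell by 0.43 (SE 0.03) and Ndufs1 by 0.39 (SE 0.05), beside astrocyte markers at −3.83. The oxidative phosphorylation call was lost without untreated replicate 1 (adjusted p = 0.12) and without Cop1 KO replicate 1 (0.068) or 2 (0.16), and with median-of-ratios factors (0.19), within a range of 0.0075 to 0.55 over the camera settings. With LPS 15 rose and 4 fell, with a median of 0.22 that became −0.34 with library size only (adjusted p = 0.066; 0.032 without LPS replicate 2; 0.012 to 0.59 over the camera settings). Between Cop1 KO and LPS 18 were lower and 2 higher, with a median of −0.29 that became 0.08 with library size only (adjusted p = 0.042; adjusted p = 0.67 with an estimated correlation). That call was lost without untreated replicate 1 or 2 (adjusted p = 0.05 each), Cop1 KO replicate 1 (0.058) or 2 (0.067) or LPS replicate 1 (0.06), within a range of 0.019 to 0.8 over the camera settings. Glycolysis had 5 higher and 7 lower of 16 in the knockout (median −0.09, or 0.04 on the nRPKM scale, adjusted p = 0.87) and 7 and 5 with LPS (median 0.05, or −0.52 with library size only, adjusted p = 0.31). Hk2, a hexokinase gene, rose by 0.84 (SE 0.04) and 0.81 (SE 0.05). NRF2 antioxidant genes had 5 higher and 5 lower of 12 in the knockout (median 0.06, or −0.13 with library size only, adjusted p = 0.8) and 4 and 8 with LPS (median −0.62, adjusted p = 0.56), and Hmox1 fell with LPS by 1.29 (SE 0.03). Cholesterol export genes had 7 higher and 3 lower of 12 in the knockout (median 0.22, mean −0.10, camera adjusted p = 0.3). With library size only 5 were higher and 5 lower (median 0.03). With LPS 4 were higher and 8 lower (median −0.16, mean 0.01, camera adjusted p = 0.84). That LPS median was −0.73 with library size only (3 and 9) and −0.02 with median-of-ratios factors (5 and 5). Scd2 fell by 3.42 (SE 0.05) in the knockout. Alternative activation genes had 3 higher and 3 lower of 10 in the knockout (median −0.16, adjusted p = 0.87) and 4 and 6 with LPS (median −0.17 with a test pointing up, adjusted p = 0.97). The mannose receptor gene Mrc1 fell in the knockout by 1.04 (SE 0.04), and Pparg fell by 4.48 (SE 0.25) with LPS.

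The p53 targets had 6 higher and 6 lower of 14 in the knockout (median 0.00, mean −0.07, adjusted p = 0.57) and 5 and 9 with LPS (median −0.35, mean 0.16, adjusted p = 0.8). Cdkn1a, a cell cycle inhibitor gene, rose by 0.51 (SE 0.03) and 2.55 (SE 0.03). The unfolded protein and integrated stress response had 7 higher and 5 lower of 15 in the knockout (median 0.14, or −0.05 with library size only, mean −0.10, adjusted p = 0.87) and 6 and 6 with LPS (median 0.10, or −0.47 with library size only, adjusted p = 0.5). Immediate early genes had 6 higher and 5 lower of 14 in the knockout (median 0.13, or −0.07 with library size only, mean −0.04, adjusted p = 0.51) and 8 and 5 with LPS (median 0.80, or 0.23 with library size only, adjusted p = 0.11; 0.0099 with library size only and 0.0099 to 0.59 over the camera settings), with Klf6 at 0.42 (SE 0.04) and 2.12 (SE 0.03). Heat shock genes had 0 higher and 4 lower of 10 in the knockout (median −0.24, adjusted p = 0.12) and 6 and 2 with LPS (median 0.45, or −0.11 with library size only, adjusted p = 0.15). Ribosomal protein genes had 10 higher and 2 lower of 22 in the knockout (median 0.13, camera adjusted p = 0.22). With library size only 1 was higher and 9 lower (median −0.07). With LPS 3 were higher and 6 lower (median −0.07, or 0.07 with median-of-ratios factors, camera adjusted p = 0.85). With LPS and library size only 1 was higher and 19 lower (median −0.63).

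Of the tests below, those of the further astrocyte list and of the weak LPS-like stimulus were written down before their own results. The list values of the main comparisons were known by then. The other tests were chosen only after the result was seen. SEs of list medians and of their differences in these tests come from the spread across genes. Genes are not independent replicates, so these SEs do not measure the spread between libraries. The lower astrocyte, oligodendrocyte lineage and neuron markers in Cop1 KO could reflect fewer cells of these kinds in the cultures: a further list of 26 astrocyte-enriched genes, none on the fixed lists, was lower in all 26 cases with a median of −3.61 (SE 0.29; −0.10 with LPS), as this explanation requires. A larger share of microglia would lower every other cell type alike, but the fibroblast median without Pdgfra lay 4.81 (SE 0.81) above the astrocyte median. With library size only the astrocyte median was −4.02, but this cannot test depth or scaling, because a single factor moves all genes alike. The median of all genes was −0.01, or −0.20 with library size only, far above the astrocyte median under either scaling. Of 1544 genes at least 4-fold lower in Cop1 KO, 1227 (79.5%) lay within 2-fold with LPS, against 66.3% of all genes. Fewer cells and lower expression per cell are not separated by these tests.

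The higher interferon-stimulated genes in Cop1 KO might follow from a larger microglial share, which alone would raise homeostatic microglia genes as much. The interferon median lay 1.5 (SE 0.19) above theirs. Homeostatic genes are no neutral gauge of that share, because with LPS 12 of 17 fell and 5 rose (median −0.78). A rise in share could be hidden in them, so the difference does not settle the question. Reads carried over from the LPS libraries could not supply the gain: the share needed, at the median 3.18%, was 71.1 times the largest share that Nos2, Il12b and Cxcl9 allow (0.045%). Whether a weak LPS-like stimulus reached the Cop1 KO cultures stays open. Some lists moved apart: homeostatic microglia genes had 12 higher and 2 lower in Cop1 KO, but 5 and 12 with LPS. Lysosome genes had 18 higher and 1 lower, but 4 and 17 with LPS. Most NF-kB genes rose in both and most cell cycle genes fell in both. Whether a weak stimulus would move these lists as LPS did was not tested. Of 435 genes strongly raised by LPS outside the interferon list, 192 (44.1%) were higher in Cop1 KO and 33 lower, against 28.1% of all genes higher. Only the listed genes were left out, so the 435 still hold interferon-inducible genes such as Ifi206. Their share is therefore not separate from the interferon rise itself. The bound written down first would have counted 44.1% against this explanation, but it was set aside after the result was seen. In 20 simulations that raised all 435 by 0.76 (log2), the observed median of the 178 with at least 1 CPM untreated, 48.3% were called. Raising all 435 by 2-fold gave 54.6% called, and 100% of the 178, so the reading depends on the rise assumed. Of these 178, 131 (73.6%) were observed higher and 24 lower, against 98.7% higher in the simulations with a rise of 0.76. Of all genes with at least 1 CPM untreated 30.4% were higher. Of the 257 below 1 CPM, 61 were higher and 9 lower, against 13.3% higher in the simulations with a rise of 0.76.

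Cop1 counts in the Cop1 KO libraries remained at 71.4% of untreated wild type. They could come from exons outside a deleted part or from cells that kept the gene, and counts per gene cannot separate the 2. Counts per exon would be needed to tell.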
